A study of Arabidopsis thaliana with 12 samples.

How the data were processed

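RNA was measured in whole Arabidopsis thaliana germinants (Columbia ecotype, 12 days old) on 12 Affymetrix Arabidopsis arrays. Per the labels, seeds were placed on wetted filter discs, 50 seeds and 2 mL of liquid per dish. Titania (TiO2) particles were compared with 0.1 mM KCl, and ceria (CeO2) particles with sterile purified water. Both particles were given at 500 mg per L. Each of the 4 groups had 3 arrays, which the labels call biological replicates for KCl and TiO2 and only replicates for water and CeO2. The labels do not state whether the particles were suspended in the same liquid as their control.

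The deposited values are log2 expression values per probe set, made by the authors with robust multi-array average (RMA: background correction, quantile normalization and median polish), per the submitters' processing notes. The RMA version is not given in the sources used here, nor are the probe definitions or whether the 12 arrays were normalized together. The value distributions of the KCl and TiO2 arrays differ from those of the water and CeO2 arrays by up to 0.435 log2 at a quantile, against at most 0.0930 between an array and the mean of its set. A pair of arrays from different sets shared at most 2 identical values, and a pair within a set at least 9. These values go with a separate normalization of the sets, which was not tested. Comparisons across the sets, as of KCl with water, would then carry its effects too. All 22746 deposited probe sets were used, with no filter on dim signals. No value was missing and no Affymetrix control probe set was among them.

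Genes were taken from the probe annotation supplied with the series and from a RefSeq gene table. Of the probe sets, 13513 were paired with 1 gene, 503 with several genes and 8730 with none. A symbol other than a locus number was available for 1580 of them. Locus numbers are used as names where no symbol was given, and a name in brackets after a locus is that of the fixed gene list.

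Differences were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over the 12 arrays and moderated by empirical Bayes. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all probe sets with a threshold of 0.05. The comparisons were TiO2 against KCl, CeO2 against water, the difference between these effects (CeO2 effect minus TiO2 effect) and KCl against water. Residual degrees of freedom were 8, with 7.63 more from the prior. The median standard error (SE) of a group difference was 0.106 log2, and 3 arrays per group limit the precision. Errors given after a change are its SE from this fit, and errors given after a group mean are the standard deviation (SD) over 3 arrays. The adjusted p-values in the text are from limma, except those said to be from Fisher's exact test.

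For gene groups, 30 lists with 684 members were written down before the data were examined, as were the comparisons, the tests and all alternatives except those said below to have been added. Only 109 members had a probe set paired with their gene alone, and 19 lists had the 3 members needed for a test; 5 lists had none. Each gene was represented by its brightest probe set of 1 gene. Lists were tested with camera (limma), preset inter-gene correlation 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members past the threshold were counted over all probe sets and adjusted over the list alone.

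Genes were named by a rule. For each particle comparison it took the 10 largest rises and 10 largest falls among probe sets past the threshold that had 1 gene with a symbol and no overlap between the groups. It also took up to 4 members past the threshold per list, and 2 members of a shifted list with none past it. For the difference of effects and for KCl against water it took 5 in each direction. Because few probe sets had a symbol, the 5 largest changes per direction among all probe sets with 1 gene were added, a choice made after the values were seen. A further 8 lists were also written after the values were seen.

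The fits were tested on simulated data with the same groups of arrays, but with noise drawn independently for each probe set. In each simulated particle comparison 22546 of the 22746 probe sets had no true difference. True differences of 1 log2 were found in 72 of 75 probe sets for TiO2 against KCl and in 50 of 53 for CeO2 against water. At 0.5 log2, 28 of 66 and 34 of 74 were found. Of the calls made in the 4 simulated comparisons, 3.05% to 7.94% were false. A list of 8 genes shifted by 0.5 log2 was found, and none of the others among 19. The simulated members were uncorrelated, whereas the estimated correlation of a tested list reached 0.684 (flavonoid and anthocyanin synthesis). The simulation therefore does not show how the list test behaves with correlated members.

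Alternatives were a second quantile normalization of the 12 arrays, centring each array on its median, leaving out the dimmest 30% of probe sets, an intensity trend with a robust prior, array weights, a replicate block, a fit of only the compared arrays, a fold threshold of 2, the mean over a gene's probe sets, other set tests, and leaving out each array in turn. Leaving out KCl replicate 3 and CeO2 replicate 3 together was added after the arrays were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probe sets without a gene were kept in all counts but are not named.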

Results

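Transcript levels were measured in 12 Arabidopsis arrays, 3 each for germinants on 0.1 mM KCl, on TiO2 particles, on water and on CeO2 particles. Each array gave log2 values for 22746 probe sets. Array medians were 5.72 log2 for the KCl and TiO2 arrays together and 5.9 for the water and CeO2 arrays. The lowest value of an array lay between 2.3 and 2.5 log2, so that genes with group means below about 4 sit near the floor of the scale, and a change to or from such a mean is a lower bound of its size. Correlations across probe sets were 0.993 to 0.997 between arrays of a group, 0.988 to 0.995 between a particle and its control, and 0.967 to 0.983 between the experiments. The main axis of a principal component analysis held 68.1% of the variance and parted the KCl and TiO2 arrays from the water and CeO2 arrays. On it, KCl replicate 3 lay at 24.6 against 35.6 and 37.0 for the others of its group, and CeO2 replicate 3 at −28.6 against −38.7 and −35.5.

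**Figure D1:**
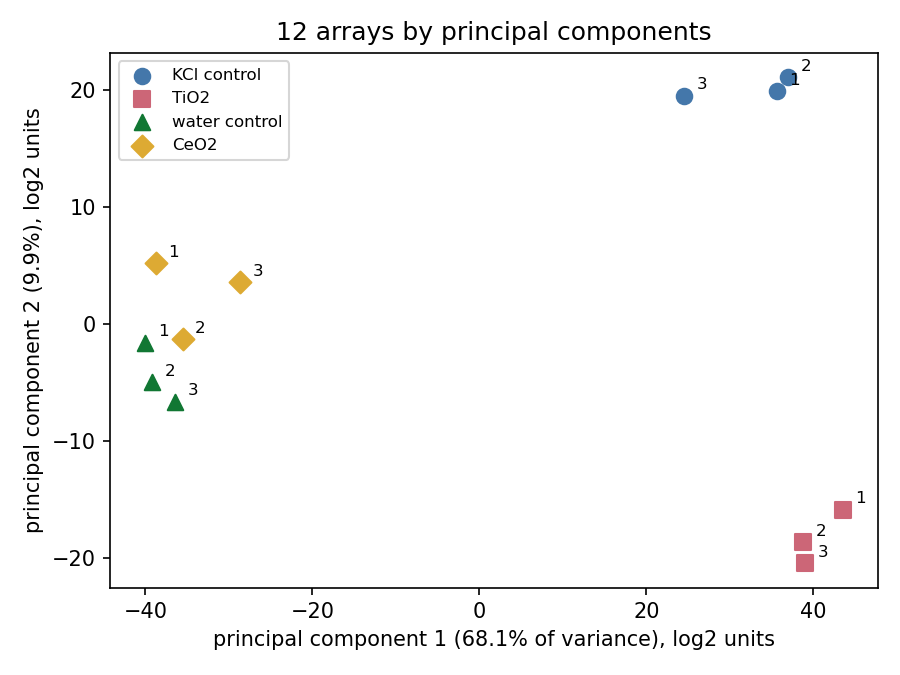
Principal component scores of the 12 arrays, with the share of variance on each axis and 1 point per array, coloured by group. The KCl and TiO2 arrays lie at the opposite end of the main axis, which holds 68.1% of the variance, from the water and CeO2 arrays.

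The comparison of TiO2 with KCl asks which transcripts differed in germinants grown on titania particles. Lower transcripts in TiO2 included M17, a late embryogenesis transcript of the maturing seed, which fell from 8.75 ± 0.49 to 6.53 ± 1.09 (log2, SD, n = 3), a 4.67-fold decrease. Genes of anthocyanin synthesis and of the iron deficiency response were lower as groups, and genes of chlorophyll and haem synthesis were higher, by a test with a preset correlation (adjusted p = 0.152, 0.147 and 0.152 with an estimated correlation). The vacuolar sugar transporter SWEET16 rose 2.34-fold, from 4.94 ± 0.22 to 6.17 ± 0.07. In all, 2407 probe sets passed the threshold, 1073 higher and 1334 lower in TiO2; with only the compared arrays in the fit the count was 1432, 560 higher and 872 lower, and without KCl replicate 1 it was 1782, 679 higher and 1103 lower. Of the 2407, 204 changed at least 2-fold, 37 higher and 167 lower.

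The largest named falls included seed transcripts. M17 fell by 2.22 ± 0.36 log2 (adjusted p = 0.000763), a size that depended on the array left out, from −1.79 without TiO2 replicate 1 to −2.83 without TiO2 replicate 3. The vicilin-like storage protein gene PAP85 fell by 1.38 ± 0.28 (adjusted p = 0.00420), and the late embryogenesis abundant gene AtLEA4-1 fell by 1.24 ± 0.25 (adjusted p = 0.00450). The asparaginase gene ASPGB1 changed by −1.74, the jasmonate-regulated gene JRG21 by −1.67, and the nitrate transporter gene NRT2.5 by −1.27. UGT84A3, a glucosyltransferase of hydroxycinnamic acids, changed by −1.40, the beta-glucosidase gene BGLU19 by −1.22, and the defence regulator WRKY22 by −1.20. Among all probe sets with 1 gene, named after the values were seen, the peroxidase gene AT5G19890 fell by 2.63 ± 0.15 log2, or 6.19-fold, the largest fall (adjusted p = 3.03e-08). AT2G43620, a chitinase family gene, changed by −2.49, AT4G12500 by −2.35 and AT1G54870 by −2.14.

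The largest named rises were smaller than the largest falls. SWEET16 rose by 1.23 ± 0.14 log2 (adjusted p = 4.10e-05), the carboxypeptidase-like gene scpl44 by 0.87, the organellar methionine aminopeptidase gene MAP1C by 0.81, and the RNA editing factor OTP81 by 0.75. The expansin EXPA15 was at 0.67 and the expansin-like EXLA1 at 0.68. COR15B, a cold-regulated chloroplast protein gene, rose by 0.68, the beta-glucosidase genes BGLU25 and BGLU46 by 0.64 and 0.63, and the subtilase gene SBT4.12 by 0.61. The largest rises among all probe sets with 1 gene, named after the values were seen, were AT2G16005 at 2.1 ± 0.15 (at least 4.31-fold, from a KCl mean of 3.55 near the floor), AT5G19110 at 1.71, AT5G47980 at 1.52, AT1G66800 at 1.44 and AT1G49500 at 1.32.

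Flavonoid and anthocyanin synthesis genes were lower in TiO2, with a median of −0.56 log2 over 6 measured members (camera adjusted p = 1.99e-06; adjusted p = 0.152 with an estimated correlation). Over all probe sets 5 of the 6 fell, and adjusted over the list alone 5 fell as well. DFR, which reduces dihydroflavonols on the way to anthocyanin, fell by 0.87 ± 0.10 (adjusted p = 3.50e-05). The anthocyanin glycosyltransferase genes AT4G14090 (UGT75C1) and UF3GT changed by −1.09 and −0.58, and the malonyltransferase gene AT5MAT changed by −0.55. In glucosinolate synthesis, 2 of 3 members fell by either count, with a list median of −0.37 (adjusted p = 0.0185; adjusted p = 0.207 with an estimated correlation). BCAT4, of methionine chain elongation, fell by 0.99, and AT2G31790 (UGT74C1) fell by 0.37. The list's call was lost without KCl replicate 3 (adjusted p = 0.0632), without TiO2 replicate 3 (adjusted p = 0.0799) and without dim probe sets (adjusted p = 0.0555), over a range of 0.00647 to 0.207 in all alternatives.

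The iron deficiency list was lower, with a median of −0.53 over 5 members (adjusted p = 0.000186; adjusted p = 0.147 with an estimated correlation). By either count, over all probe sets or adjusted over the list alone, 4 of the 5 fell. The transcription factor gene BHLH101 changed by −0.88 ± 0.11 and the iron homeostasis regulator PYE by −0.43, the peptide gene AT1G47400 (IMA1) by −0.80, and AT3G13610 (F6'H1), of coumarin synthesis, by −0.53. In the oxidative and mitochondrial stress list 2 of 4 members fell by either count, with a median of −0.46 (adjusted p = 0.0134; adjusted p = 0.185 with an estimated correlation). These were the zinc finger gene STZ (ZAT10), which fell by 1.42, and the alternative NADH dehydrogenase gene NDB4, which fell by 0.73. That list's call was lost without KCl replicate 3 (adjusted p = 0.0632) and without TiO2 replicate 1 (adjusted p = 0.0907), over a range of 0.00361 to 0.185 in all alternatives.

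Chlorophyll and haem synthesis genes were higher by a median of 0.25 over 8 members (adjusted p = 0.000693; adjusted p = 0.152 with an estimated correlation). Over all probe sets 2 rose, and adjusted over the list alone 5 did. PORB, which reduces protochlorophyllide in light, rose by 0.51 ± 0.10 and GSA1, of 5-aminolevulinate synthesis, by 0.30. Photosystem and light harvesting genes were lower, with a median of −0.23 over 8 members (adjusted p = 0.000356; adjusted p = 0.152 with an estimated correlation). Over all probe sets 3 fell, and adjusted over the list alone 4 did. The light harvesting genes LHCB4.3 and LHCB4.2 changed by −0.88 and −0.35, and the photosystem gene PSAE-1 changed by −0.34.

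The other 13 tested lists had adjusted p of 0.133 or more. Members went both ways among the antioxidant enzymes, where over all probe sets 1 of 8 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell. AT3G52960 (PRXIIE), a peroxiredoxin gene, rose by 0.30, while ATMDAR2, of ascorbate recycling, changed by −0.45 and the copper chaperone CCS by −0.34. Of 8 glutathione S-transferase genes, GSTU26 rose by 0.52 and GSTU25, GSTU22 and GSTU18 changed by −1.12, −1.05 and −0.42, and adjusted over the list alone 2 rose and 3 fell. That list (adjusted p = 0.136; adjusted p = 0.512 with an estimated correlation) was past the threshold with the replicate block (adjusted p = 0.0400) and without KCl replicate 2 (adjusted p = 0.0266). The abscisic acid list passed without KCl replicate 3 (adjusted p = 0.0317) and the heat shock list without TiO2 replicate 1 (adjusted p = 0.0447), with 0.385 and 0.231 by an estimated correlation over all arrays. Of 9 auxin genes, WES1 (GH3.5), which conjugates auxin, changed by −0.82 and IAA20 by −0.38, with 2 rises and 3 falls adjusted over the list alone. Single members rose in the lists of DNA replication (ICU2, 0.36), heat shock (AT5G37670, HSP15.7, 0.58), abscisic acid and cold (COR15B) and cell wall loosening (EXPA15). Adjusted over the list alone the rises numbered 1 in each of these but cell wall loosening, with 2 rises and 1 fall. The root hair list had 1 fall over all probe sets, AT4G26010 (PRX44) by 0.44, and 1 rise and 1 fall adjusted over the list alone.

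Of the 57 named TiO2 changes, 18 lost their call without some single array, with adjusted p up to 0.188; leaving out KCl replicates 1, 2 and 3 ended 12, 11 and 6 of them, and TiO2 replicates 1, 2 and 3 ended 7, 11 and 14. These were IMA1, UGT74C1, F6'H1, PRXIIE, PRX44, HSP15.7, BGLU46, CCS, EXLA1, GSA1, GSTU18, GSTU26, IAA20, ICU2, LHCB4.2, NDB4, PSAE-1 and PYE, and PSAE-1 (0.0862), CCS (0.0604), ICU2 (0.0711) and UGT74C1 (0.0603) also lost it after a second quantile normalization (adjusted p in brackets).

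**Figure D2:**
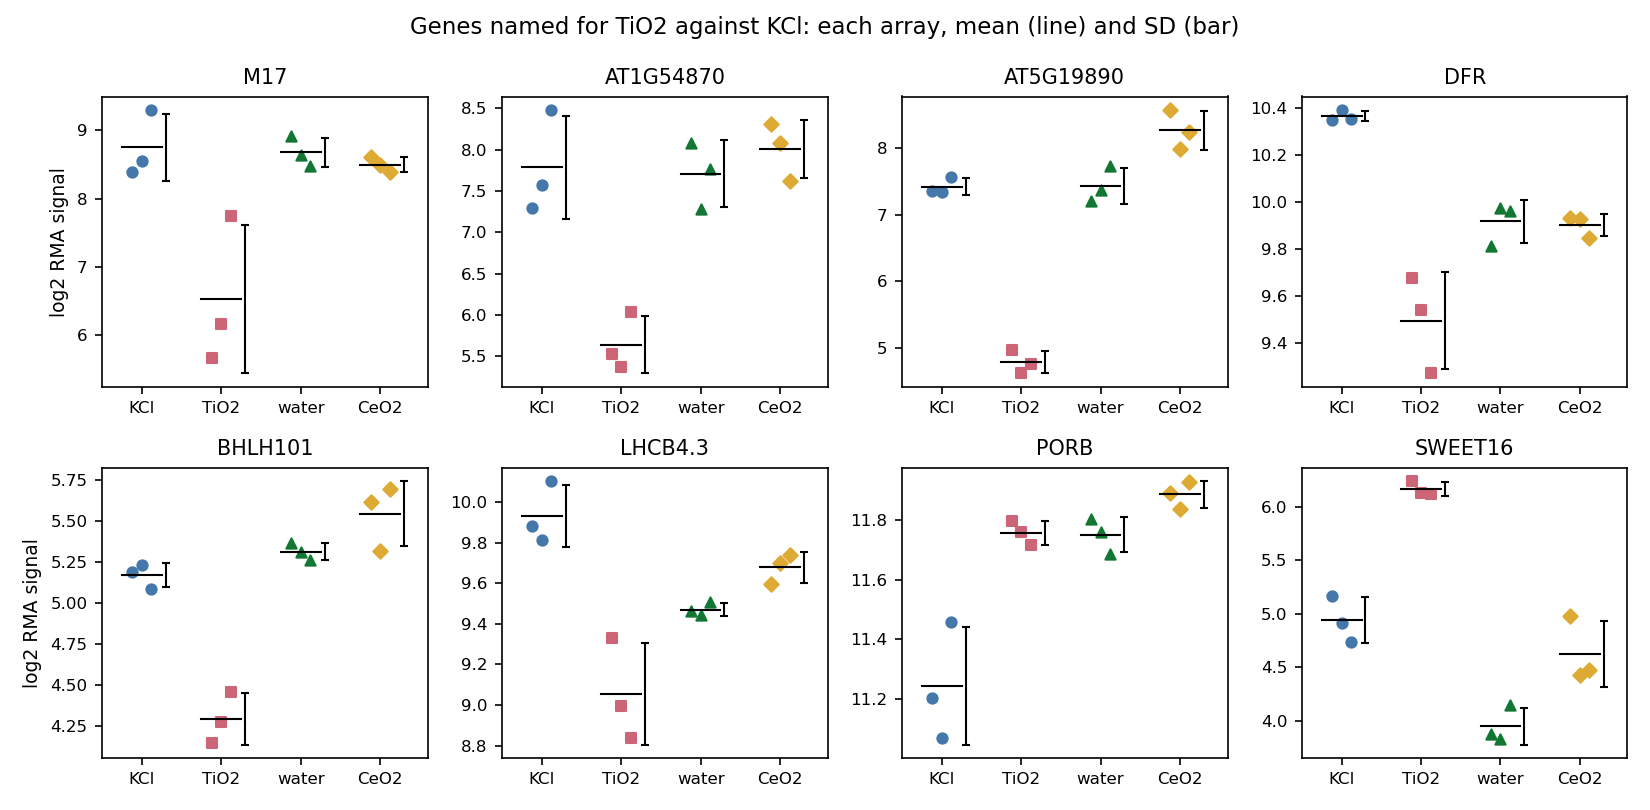
Log2 RMA signal of M17, AT1G54870, AT5G19890, DFR, BHLH101, LHCB4.3, PORB and SWEET16 in the 4 groups, with points for arrays, a line for the mean and bars for the SD. PORB and SWEET16 are higher in TiO2 than in KCl, by 0.51 and 1.23 log2, and the other genes are lower, AT5G19890 by −2.63 log2.

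The comparison of CeO2 with water asks which transcripts differed in germinants grown on ceria particles. The root hair genes that were measured, 3 of 18 in the list, were higher in CeO2 as a group. The salicylic acid and defence list, with 3 of 26 measured, was lower. With an estimated correlation their camera adjusted p were 0.0122 and 0.109. The cell wall gene XTH26, a xyloglucan endotransglucosylase, rose 4.82-fold, from 5.55 ± 0.29 to 7.82 ± 0.06 log2 (SD, n = 3). AT1G26380, of the berberine bridge enzyme family, fell at least 18.6-fold, from 8.04 ± 0.12 in water to 3.83 ± 0.13 in CeO2, near the floor, and its mean was 3.44 in KCl and 3.43 in TiO2. In all, 550 probe sets passed the threshold, 286 higher and 264 lower, and 142 of them changed at least 2-fold, 63 higher and 79 lower. The balance over all 550 turned without some single arrays: 185 were higher and 200 lower without water replicate 1, 208 and 223 without water replicate 3, 205 and 221 without CeO2 replicate 1, and 173 and 209 without CeO2 replicate 3.

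The cell wall loosening list was not past the threshold in CeO2 (adjusted p = 0.289), with none of 9 members past it over all probe sets and 1 rise adjusted over the list alone. Of the named rises, XTH26 rose by 2.27 ± 0.12 log2 (adjusted p = 9.98e-09), the root hair expansin EXPA18 by 1.44 ± 0.12 (adjusted p = 2.13e-06), and EXPA7, also of root hairs, by 0.96 ± 0.14 (adjusted p = 0.000352). TET12, a tetraspanin gene, rose by 1.41, the endoglucanase gene GH9C1 by 1.16, the cytochrome P450 gene CYP718 by 1.09, the extensin-type gene HRGP1 by 0.94, and the peptide gene RALFL22 by 0.85. The metal transporter gene ZIP9 rose by 0.91 ± 0.12 and the carnitine transporter gene OCT1 by 0.81 ± 0.20 (adjusted p = 0.0401). The metallothionein gene MT1C rose by 0.57 (adjusted p = 0.0474). Among all probe sets with 1 gene, named after the values were seen, AT4G11190 rose by 2.45, the peroxidase gene AT1G34510 by 1.87, AT5G04120 by 1.60 and AT4G33720 by 1.57.

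The root hair list rose by a median of 1.26 log2, with all 3 measured members past the threshold by either count, over all probe sets or adjusted over the list alone (camera adjusted p = 7.38e-13; adjusted p = 0.0122 with an estimated correlation). The third member, the peroxidase gene AT4G26010 (PRX44), rose by 1.26 ± 0.12. These 3 genes were also higher in KCl than in water, by 1.25 for EXPA18, 0.51 for EXPA7 and 0.75 for AT4G26010. XTH26 was higher in KCl than in water too, by 0.79, and had a CeO2 mean of 7.82 against 6.34 in KCl and 5.94 in TiO2, and GH9C1 one of 9.29 against 7.89 and 7.95.

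Of the falls, AT1G26380 changed by −4.21 ± 0.10 log2 (adjusted p = 4.76e-13) and the lectin-like gene AT3G16530 by −4.01 ± 0.11, or 16.2-fold (adjusted p = 1.82e-12), both chosen after the values were seen. The same rule added the chitinase family gene AT2G43590, which fell by 2.52, the peroxidase gene AT1G14550, which fell by 2.29, and AT1G36640, which fell by 2.23. CHI, here the chitinase gene AT2G43570 and not chalcone isomerase, changed by −2.01 ± 0.10 (adjusted p = 5.63e-09), the osmotin gene OSM34 by −1.72, YLS5 by −1.62, AR781 by −1.27, and the cytochrome P450 gene CYP71B6 by −1.22. The protease genes SBT3.5 and NANA changed by −1.03 and −1.02. PUB23 and PUB24, ubiquitin ligases that dampen immune responses, changed by −0.93 and −0.78. WRKY53, a regulator of senescence and defence, changed by −0.74 and WRKY6 by −0.40. AT3G13610 (F6'H1) fell by 0.98 and was the 1 iron list member of 5 past the threshold, by either count.

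The salicylic acid and defence list was lower, with a median of −0.42 over 3 members (adjusted p = 0.00586; adjusted p = 0.109 with an estimated correlation). Over all probe sets 1 fell, WRKY53, and adjusted over the list alone 2 fell. Chlorophyll and haem synthesis genes were lower, with a median of −0.22 over 8 members (adjusted p = 0.00528; adjusted p = 0.184 with an estimated correlation). Over all probe sets none fell, and adjusted over the list alone 4 did; HEME2 was at −0.28 (adjusted p = 0.184) and GSA1 at −0.25 (adjusted p = 0.237). The abscisic acid, drought and cold list was higher by a median of 0.35 over 4 members (adjusted p = 0.00571; adjusted p = 0.170 with an estimated correlation). COR15A rose by 0.49, as the only member over all probe sets, and adjusted over the list alone 2 rose. That list's call was lost without CeO2 replicate 1 (adjusted p = 0.0557), over a range of 0.00228 to 0.329 in all alternatives. The other 15 lists had adjusted p of 0.289 or more. Of these, oxidative and mitochondrial stress passed without water replicate 3 (adjusted p = 0.0112) and cell wall loosening without CeO2 replicate 2 (adjusted p = 0.0308), with 0.682 and 0.397 by an estimated correlation over all arrays.

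Of the 36 genes named for CeO2, 28 differed in the same direction between KCl and water, a difference that shares the water arrays with this comparison; of all 550 probe sets past the threshold in CeO2 72.7% did, and of the 22196 others 29.4%. The calls of COR15A, MT1C, OCT1 and WRKY6 were lost without some single array (water replicates 1 to 3, CeO2 replicates 1 and 3), with adjusted p up to 0.238.

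**Figure D3:**
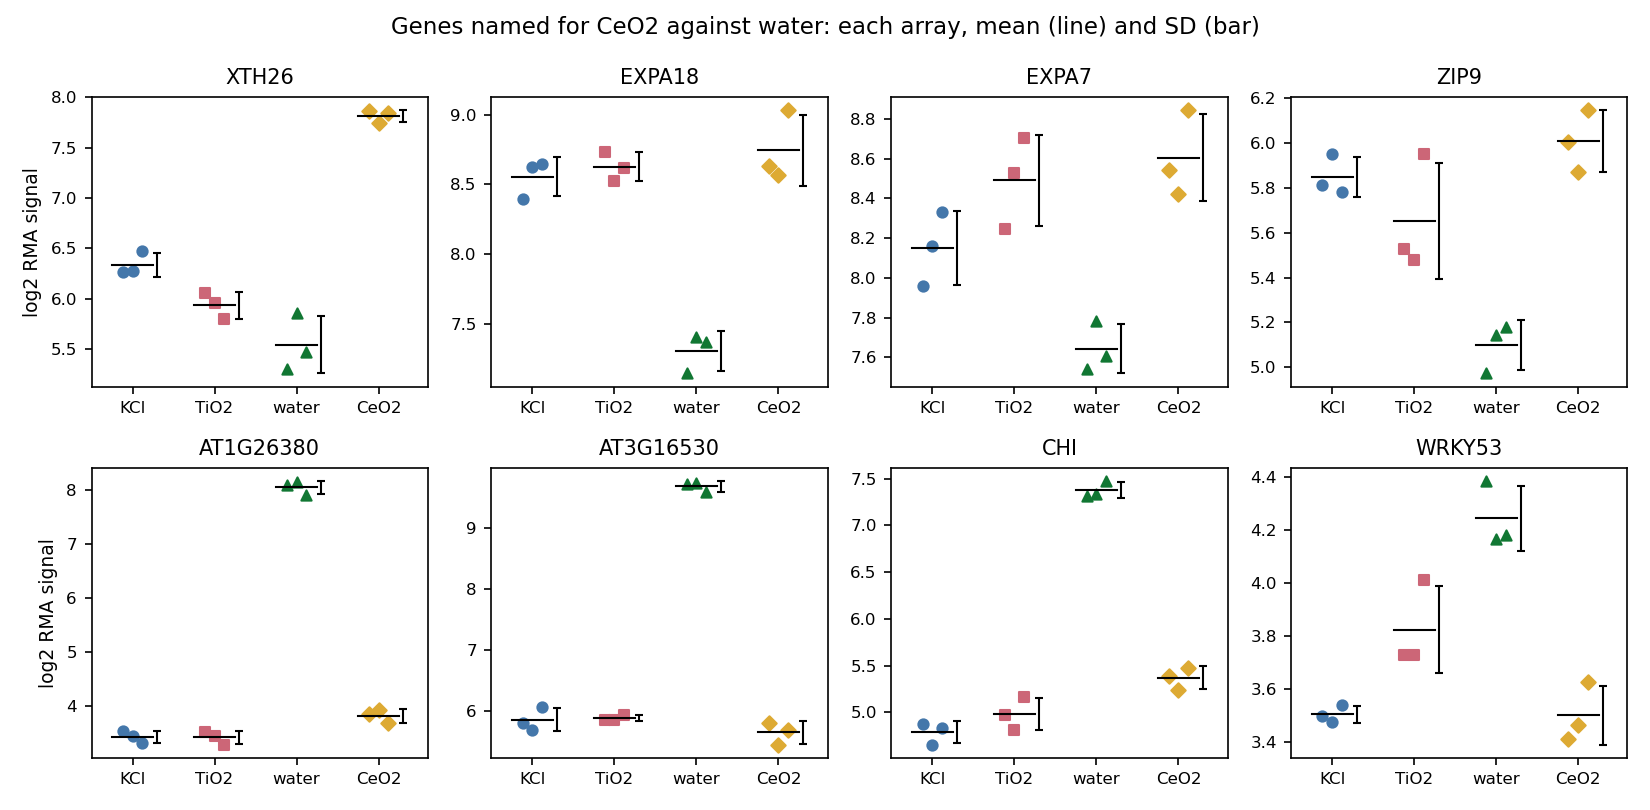
Log2 RMA signal of XTH26, EXPA18, EXPA7, ZIP9, AT1G26380, AT3G16530, CHI and WRKY53 in the 4 groups, with points for arrays, a line for the mean and bars for the SD. The CeO2 mean of AT1G26380 (3.83) lies near those of KCl (3.44) and TiO2 (3.43), and the water mean is 8.04.

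The difference between the particle effects asks whether ceria and titania acted alike against their own controls. The test of the CeO2 effect minus the TiO2 effect was passed by 1833 probe sets, 1056 more positive and 777 more negative under CeO2. Particle, control liquid and set of arrays go together in this design, so these differences cannot be credited to the particles alone. XTH26 had a difference of 2.67 ± 0.18 log2 (adjusted p = 1.54e-07), from a rise in CeO2 and a value of −0.40 in TiO2. AT5G19890 differed by 3.46 ± 0.21, from a rise of 0.83 in CeO2 (adjusted p = 0.0042) and the fall in TiO2. AT1G26380 differed by −4.20 ± 0.14, but its KCl mean of 3.44 lay near the floor, so that a large fall in TiO2 could not have been seen.

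More positive under CeO2 were ASPGB1 by 2.00, ECS1 by 1.71, and UGT84A3 by 1.71. M17 differed by 2.04 ± 0.51 (adjusted p = 0.0199), from 1.61 without TiO2 replicate 1 to 2.65 without TiO2 replicate 3, and that call was lost without CeO2 replicate 1 (0.0525), TiO2 replicate 2 (0.0582) or water replicate 3 (0.0581) and with an intensity trend and robust prior (adjusted p = 0.131). More negative under CeO2 were CHI by −2.20, YLS5 by −1.99, CYP71B6 by −1.39, BGLU46 by −1.13, and GH3.3, which conjugates auxin, by −1.63. Among all probe sets with 1 gene, chosen after the values were seen, AT4G12500, AT2G43620 and AT1G54870 differed by 3.24, 2.54 and 2.44. AT3G16530, AT1G26250, AT1G14550 and AT1G36640 differed by −4.03, −2.65, −2.28 and −2.23. For AT1G14550 and AT1G36640 the KCl means of 3.85 and 3.13 were near the floor as well.

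Of the fixed lists, root hair markers differed by a median of 1.37 (adjusted p = 6.50e-06; adjusted p = 0.0968 with an estimated correlation), with 2 of 3 members past the threshold over all probe sets and 3 adjusted over the list alone. Flavonoid and anthocyanin genes differed by 0.56 (adjusted p = 1.73e-05; adjusted p = 0.230 with an estimated correlation), with 2 of 6 past over all probe sets and 5 adjusted over the list alone. Chlorophyll and haem synthesis differed by −0.47 (adjusted p = 1.87e-05; adjusted p = 0.0968 with an estimated correlation), with 5 of 8 past over all probe sets and 6 adjusted over the list alone. Photosystem genes differed by 0.13 (adjusted p = 0.00544; adjusted p = 0.230 with an estimated correlation), with 1 of 8 past over all probe sets and 2 adjusted over the list alone. The iron list had an adjusted p of 0.118, the lowest of the other 15, and passed without CeO2 replicate 2 (adjusted p = 0.0494), as glutathione S-transferases did without KCl replicate 2 (adjusted p = 0.0438). For the salicylic acid list the median was 0.01, the mean −0.33 and the direction of the test down (adjusted p = 0.278).

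Of the probe sets past the threshold in the particle comparisons, 193 were in both. These comparisons share no arrays, but they share the estimate of spread of each probe set. The same direction was found for 103 of them, where 29.0 would be expected from independent draws, and the opposite direction for 90, where 29.2 would be. Fisher's exact test over all probe sets gave adjusted p = 1.46e-24 for lower in TiO2 and higher in CeO2 (70 probe sets), 2.42e-18 for lower in both (58), 1.49e-12 for higher in both (45) and 0.0389 for higher in TiO2 and lower in CeO2 (20). These p-values treat probe sets as independent draws, which they are not, and a probe set of small spread can pass in both comparisons. Every pair of directions lay above expectation, by ratios of 1.61 to 4.17, so the p-values do not show shared or opposed responses. Across probe sets, which are not independent replicates, the log2 changes had a Pearson correlation of −0.0687 and a Spearman correlation of −0.111.

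**Figure D4:**
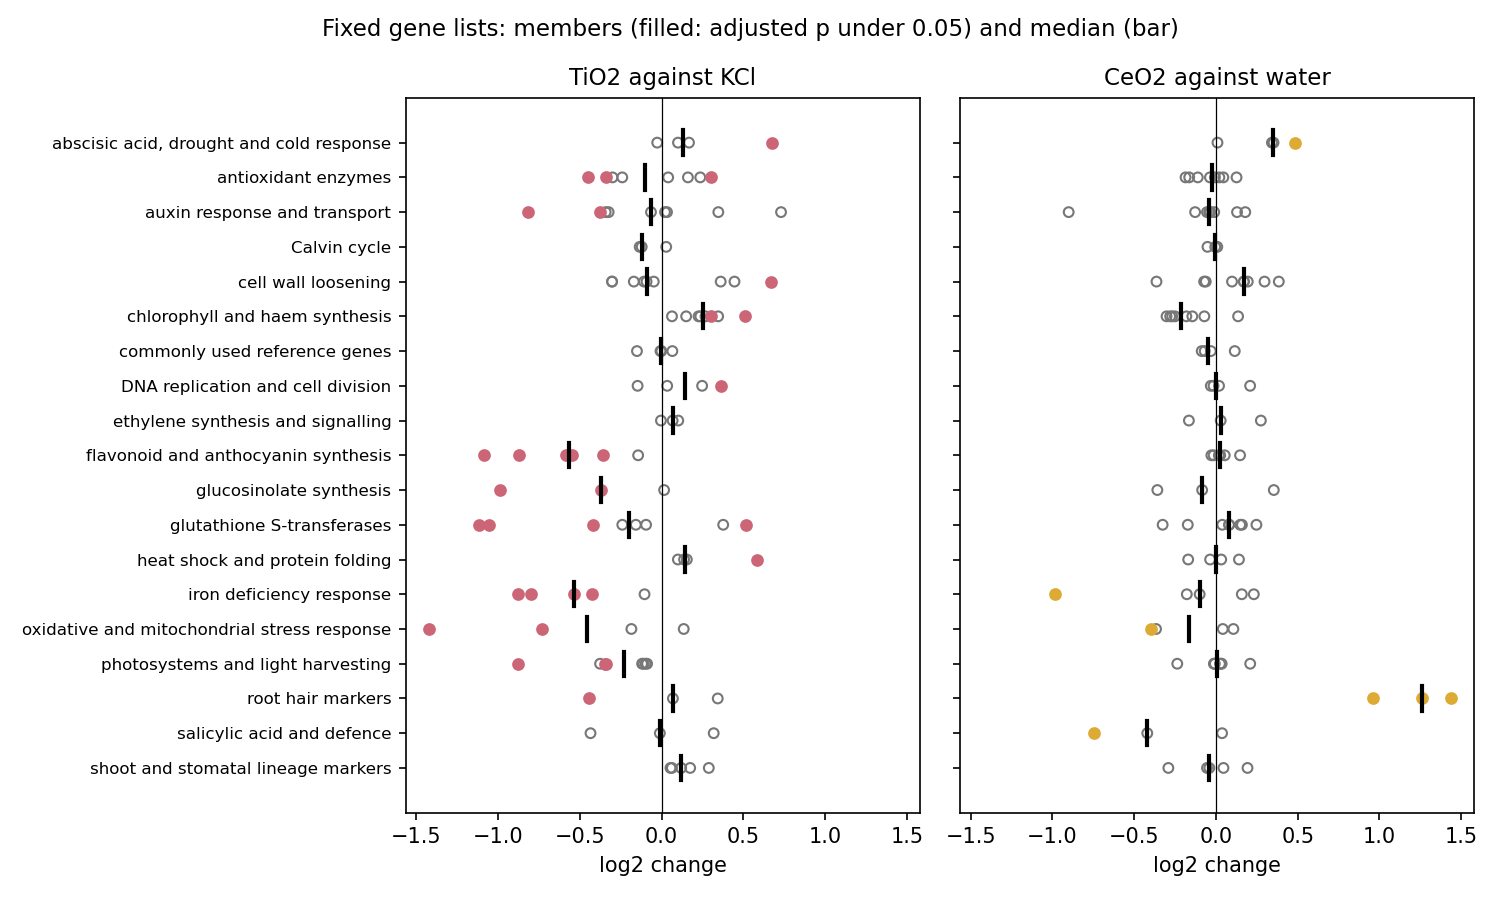
Median log2 change of each tested gene list in the particle comparisons, with 1 panel per comparison and the lists on the vertical axis. The root hair list is at 1.26 in CeO2 against water, and the flavonoid list is at −0.56 in TiO2 against KCl.

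The comparison of KCl with water asks how the control groups differ, and it joins the medium with the set of arrays, so that these cannot be told apart. It gave 11285 probe sets past the threshold, 5285 higher and 6000 lower in KCl. The balance depended on the scale, since centring each array on its median gave 9456 higher and 4021 lower, and a second quantile normalization 5810 and 5501. Of the 11285, 1262 changed at least 2-fold, 374 higher and 888 lower. Chloroplast-encoded genes were among the largest differences. The NADH dehydrogenase-like subunit gene ndhE was higher by 3.43 ± 0.37 log2, atpI by 2.94, rps4 by 2.81, psaI by 2.43 and psbN by 2.28, and petG was lower, at −3.29. The SD of the KCl arrays was 1.16 for ndhE and 0.12 for psbN. Without KCl replicates 1 and 3 in turn, the difference was 2.97 and 4.08 for ndhE, 2.51 and 3.70 for atpI, and 2.00 and 3.07 for psaI.

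Several genes that were lower in CeO2 than in water were lower in KCl than in water too. AT1G26380 differed by −4.60 ± 0.10, AT3G16530 by −3.81, the peroxidase gene AT1G14550 by −3.00, CHI by −2.59, YLS5 by −2.30 and OSM34 by −2.17. The ubiquitin protease gene UBP23 differed by −2.36, and AT4G11190 by 2.80. The abscisic acid, drought and cold list was lower in KCl, with a median of −1.31, with all 4 members past by either count (adjusted p = 0.00501; adjusted p = 0.169 with an estimated correlation). Heat shock genes were lower, with a median of −0.93 (adjusted p = 0.0201; adjusted p = 0.169 with an estimated correlation), with 3 of 4 past over all probe sets and 4 adjusted over the list alone. Root hair markers were higher by 0.75, with all 3 members past by either count (adjusted p = 0.0454; adjusted p = 0.435 with an estimated correlation). That list's call was lost after a second quantile normalization (0.0563), after median centring (0.0899), and without KCl replicate 3, water replicate 1 or water replicate 3 (up to 0.0641), over a range of 0.000342 to 0.435 in all alternatives. The other 16 lists had adjusted p of 0.0640 or more. Of these, the auxin list passed after median centring (0.0379), without dim probe sets (0.0496), without KCl replicate 3 (0.0229) and without water replicate 2 (0.0339). Chlorophyll and haem synthesis passed after a second quantile normalization (0.0169), and both had 0.435 by an estimated correlation.

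Reference genes stayed within less than 1 log2 over the 12 arrays. Means and SDs were 7.52 ± 0.12 for TIP41, 8.96 ± 0.20 for UBC21, 12.6 ± 0.14 for GAPC2 and 8.22 ± 0.17 for SAND, and none passed the threshold in any comparison. The root tissue marker PYK10, the only measured member of its list, was at 0.09 in TiO2, 0.01 in CeO2 and 0.12 in KCl against water, none past the threshold.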

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

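Of the tests in this part, those of the water arrays and of the scale of the arrays were chosen after the result was seen, as were the added gene lists and the genes named by locus. Results are given here because the effects of CeO2 and TiO2, each against its own control, differed by a test of the difference itself. With 3 arrays per group, no formal test for single arrays out of place was made. KCl replicate 3 correlated at 0.9934 and 0.9933 with the others of its group, which correlated at 0.9975 with each other. The difference was past the threshold for 1833 probe sets, and 1 of 100 drawn splits of the arrays, the real one, gave as many. The highest other split gave 1072. Both sets of arrays were regrouped in these splits, so they bear on no effect of either particle. They cannot show whether the effects of the particles are unequal. For the 3-against-3 comparisons the 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, gave the count, which was 2407 for TiO2 against KCl, 550 for CeO2 against water and 11285 for KCl against water, and the highest other was 0.

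Of the 93 genes named for the particles or their difference, 58 differed, 34 with a higher value under CeO2 and 24 with a lower one. The choice of genes raised that share, since 19 of them were named for passing this test. Others were named for a large change in a particle comparison. Over all probe sets, 8.06% passed. Values are the CeO2 effect minus the TiO2 effect in log2. Genes that rose in CeO2 included XTH26 (2.67), TET12 (1.60), EXPA18 (1.37), RALFL22 (1.25), GH9C1 (1.11), HRGP1 (0.98), AT4G26010 (1.70) and AT1G34510 (1.18). Genes that fell in TiO2 included M17 (2.04), AtLEA4-1 (1.27), AT1G54870 (2.44), ASPGB1 (2.00), UGT84A3 (1.71), JRG21 (1.49), NRT2.5 (1.43), WRKY22 (1.28) and BGLU19 (0.96). Differences were also found for AT5G19890 (3.46), AT4G12500 (3.24), AT2G43620 (2.54), AT4G33720 (2.17), AT5G04120 (1.91), ECS1 (1.71), AT4G11190 (1.18) and CYP718 (1.09). Members of the fixed lists were BCAT4 (1.34), AT4G14090 (1.14), DFR (0.86), BHLH101 (1.11), ZIP9 (1.11), GSTU22 (1.09), LHCB4.3 (1.09), WES1 (0.80), ATMDAR2 (0.58), GSA1 (−0.55), HEME2 (−0.52), COR15B (−0.67) and WRKY53 (−1.06).

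Lower under CeO2 were AT1G26380 (−4.20), AT3G16530 (−4.03), AT1G26250 (−2.65), AT1G14550 (−2.28), AT1G36640 (−2.23), AT2G16005 (−2.22), CHI (−2.20), YLS5 (−1.99) and GH3.3 (−1.63). Smaller negative values were those of AT5G19110 (−1.56), CYP71B6 (−1.39), AT1G66800 (−1.15), BGLU46 (−1.13), NANA (−1.0), MAP1C (−0.99), AT1G49500 (−0.87), OTP81 (−0.85), scpl44 (−0.66), PUB23 (−0.64) and SBT3.5 (−0.62). For AT1G26380, AT1G14550 and AT1G36640 the KCl mean was near the floor of the arrays, so that a large fall in TiO2 could not have been seen. The KCl mean of WRKY53 was near the floor too. Its difference (−1.06) was larger in size than its CeO2 fall (−0.74), so its TiO2 change lay above 0. List medians that differed were −0.47 for chlorophyll and haem synthesis, 0.56 for flavonoids, 0.13 for photosystems and 1.37 for root hair markers; with an estimated correlation their adjusted p were 0.0968, 0.230, 0.230 and 0.0968, none past the threshold. Among the added lists they were −0.097 for berberine bridge oxidases, 0.11 for class III peroxidases, 1.04 for the longer root hair list, 0.85 for seed maturation and 1.45 for suberin. With an estimated correlation the adjusted p were 0.0996, 0.0757, 0.0117, 0.0879 and 0.0117, past the threshold for root hair and suberin. The berberine bridge call was also lost without dim probe sets (0.312), TiO2 replicate 2 (0.0590) or water replicate 2 (0.0521). These lists hold genes seen beforehand: over unseen members the medians were 0.0027, 0.079, 0.32, 0.47 and 0.50.

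The CeO2 changes of at least 2-fold share a pattern: among the 79 lower in CeO2, 77 were also lower in KCl than in water, and for 97.5% the water mean lay farther from the mean of the KCl and TiO2 arrays than the CeO2 mean did. This is what water arrays that stand apart from all other groups would give, and it may mean that a state of the water samples, rather than the particles, made part of these falls; for the 63 rises the share was 73.0%, which leaves it open. Both differences use the water arrays, so part of the share is built in. For a fall, the share counts the probe sets whose water and CeO2 values lie on average above those of KCl and TiO2. It thus follows the offset between the sets of arrays and cannot show that the water arrays alone stand apart. The like share with the KCl control, 16.2% among 167 falls in TiO2, follows the same offset and is no check on it. Over all probe sets the shares were 50.6% with water and 45.8% with KCl. The water and CeO2 arrays lay within 0.0930 log2 of the mean of their set at every quantile. Set against changes of at least 1 log2, this argues against the scale of these arrays as the source of the 2-fold changes. It covers CeO2 against water alone, not the comparison with the KCl and TiO2 arrays. After a second quantile normalization 100% of these changes stayed past the threshold, but it could hardly have ended them and decides nothing. An effect of ceria itself stays open and cannot be parted from a state of the water samples by these arrays.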

How the results depend on the processing

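Leaving out KCl replicate 3 and CeO2 replicate 3 together, and all alternatives of the added lists, were chosen after the data were seen. With only the compared arrays in the fit, TiO2 against KCl gave 1432 probe sets in place of 2407. CeO2 against water gave 606 in place of 550, and KCl against water 10869 in place of 11285. The cause was not tested. A fold threshold of 2, which by construction keeps fewer, gave 204, 142, 442 and 1262 for TiO2, CeO2, their difference and KCl against water with an adjusted p, and 204, 142, 449 and 1262 with an unadjusted one. Of list shifts, 17 were past the threshold with camera, 1 with an estimated correlation, 33 with directional fry and 30 with mixed fry, which test another question. Leaving out each array gave 1782 to 2551 probe sets for TiO2, 382 to 469 for CeO2, 1434 to 2072 for the difference and 9754 to 11180 for KCl against water, 16 to 19 list shifts, and 111 to 123 calls of 125 named ones; the cause was not tested. The chloroplast-encoded list, not past the threshold with all arrays in TiO2 or in the difference of effects, passed in opposite directions without single KCl arrays, and the cause was not tested: in TiO2 its median was −0.40 (3.32e-08) without KCl replicate 3 and 0.27 (0.00228) without KCl replicate 1, and in the difference −0.37 (0.000445) without KCl replicate 1 and 0.29 (0.00132) without KCl replicate 3. That list also passed in TiO2 without TiO2 replicate 2 (median −0.13, camera adjusted p = 0.0279). In the difference it passed without TiO2 replicate 3 (−0.22, 0.0194). A second quantile normalization gave 2418, 563, 1853 and 11311 probe sets for TiO2, CeO2, the difference and KCl against water. Array weights gave 2830, 757, 2342 and 12619. Centring each array on its median moved the median of all probe sets in KCl against water from 0.0036 to 0.18 log2, so that 70.2% of 13477 calls were higher in KCl, against 46.8% of 11285. Whether the replicate numbers pair the arrays stays open. Deviations of the same number correlated at 0.046 to 0.274 in the TiO2 set and 0.0022 to 0.302 in the CeO2 set. Those of different numbers correlated at −0.288 to 0.221 and at −0.229 to 0.170. Between the controls, the same number gave −0.017 to 0.010. With the replicate block the counts were 2886, 647, 2148 and 11299, no named gene changed its call, and 1 fixed and 1 added list were gained, glutathione S-transferases in TiO2 (adjusted p = 0.0400) and chloroplast-encoded genes in CeO2 (adjusted p = 0.00211). Without KCl replicate 3 and CeO2 replicate 3 together the counts were 2462, 440, 1669 and 10956. Of 127 named results, 123 kept their call under a second quantile normalization and 125 under an intensity trend with a robust prior, and none turned its direction. Signals near 2.3 to 2.5 log2, the floor of the arrays, limit how large a fall can be seen in dim genes.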

Other observations

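The gene lists of this part and all their tests were chosen after the values were seen, and only the tests that leave out 1 array were written down before their own results were. The lists hold genes whose values prompted them, so that their tests are not independent of these, and members not seen beforehand are given apart. Class III peroxidases had 12 falls and 1 rise among 55 members in TiO2 against KCl (adjusted p = 0.0607 with an estimated correlation), and the 46 unseen members had a median of −0.15 with 9 falls. In CeO2 against water the unseen members went both ways, with 3 rises and 4 falls. Suberin genes, of the lipid barrier in root cell walls, had 7 falls among 10 members in TiO2 (adjusted p = 0.0197 with an estimated correlation). Their median was −1.68 over 4 seen members and −0.31 over 6 unseen ones, 3 of which fell. In CeO2 2 of the 6 unseen members rose, with a median of 0.22.

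Chitinases and thaumatin-like proteins had 10 falls and 2 rises among 34 members in TiO2, but the 28 unseen members had a median of −0.00026, with 5 falls and 2 rises, and in CeO2 1 of them fell. Berberine bridge enzyme-like oxidases had 6 falls among 22 members in CeO2, 5 of them among the 6 seen genes, and the 16 unseen members had a median of 0.036. Chloroplast-encoded genes were higher in KCl than in water by a median of 1.28 over 69 members, with 49 higher and 4 lower (adjusted p = 0.468 with an estimated correlation). For CeO2 against water their median was −0.092 (camera adjusted p = 0.0725; adjusted p = 0.717 with an estimated correlation). That list was past the threshold with the replicate block (0.00211), a second quantile normalization (0.0384) or median centring (0.0485), and without water replicate 1 (0.0205), water replicate 3 (0.0163) or CeO2 replicate 2 (0.000727).

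Seed maturation genes were lower in TiO2 than in KCl with a median of −0.60 over 37 members, 21 of which fell (adjusted p = 3.50e-19; adjusted p = 0.0777 with an estimated correlation). No single array made this, since the smallest median without 1 array was −0.53. Among the 29 members whose values had not been seen when the list was written, 93.1% lay below 0, with a median of −0.37 and 13 falls, against −1.66 and 8 falls for the 8 seen ones. A candidate explanation is that the TiO2 dishes held less unsprouted or late seed, which that share goes with. A direct effect of titania on these transcripts in growing tissue stays open as well, since no sample parts seed from germinant. In CeO2 the list had a median of 0.086 and 1 member rose (adjusted p = 0.00156; adjusted p = 0.459 with an estimated correlation), a call lost without water replicate 2 or CeO2 replicate 1 (up to 0.193).

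Root hair transcripts were higher in CeO2 than in water by a median of 1.09 over a longer list of 10 members, with 7 rises (adjusted p = 0.00312 with an estimated correlation). The smallest median without 1 array was 1.0, so no single array made it. For the 3 measured root hair genes of the fixed list, which were not chosen by their values, the median rise was 1.26. More root in the CeO2 samples is argued against as the whole cause of the rise of these 3 genes. The 16 root tissue genes had a median of −0.014, with 3 rises and 1 fall. Their mean was 0.11 and the direction of the test up (adjusted p = 0.0254; adjusted p = 0.357 with an estimated correlation), a call lost without water replicate 1, CeO2 replicate 1 or CeO2 replicate 3 (up to 0.183). The 4 members of the longer list not seen before had a median of only 0.19 with 1 rise. That is too near the root tissue values to decide on more root for them. More or longer root hairs may stand behind the rise of the longer list (1.0 at the lowest, as above), but those 4 members hardly shared it. The KCl arrays also lay above water, by a list median of 0.48 (adjusted p = 0.468 with an estimated correlation).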
